A study of Mus musculus with 7 samples.

How the data were processed

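Messenger RNA sequencing had been done on fetal liver at 12.5 days post coitum from 4 wild-type and 3 Pcbp2 knockout samples of the mouse. Per the labels, total RNA was extracted with Trizol and made into TruSeq stranded mRNA libraries. The processing notes of the submitters name cutadapt 1.4.2, TopHat2, HTSeq, DESeq2 and DESeq, and the genome build mm10; their settings are not given in the sources used here. The deposited files hold raw read counts per gene for each library, for 38924 genes, followed by 5 HTSeq summary lines on reads that were not assigned. The deposited table of the authors compares knockout with wild type. As deposited by the authors, its baseline signal is a mean of normalized counts over all samples, its change a log2 fold change with a standard error, its test score a Wald statistic, and its p-value is given unadjusted and adjusted, for 15548 genes. The sign of the authors' log2 fold change, knockout over wild type, was checked against the counts.

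Gene names came from the authors' table for 15548 identifiers and from GENCODE M21, on the same genome build, for another 22194, while 1182 had no name. Coordinates came from that release and cover 16075 of the tested genes. The release the authors counted on is not given in the sources used here, and identifiers were matched to it without their version.

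Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 16226 and removed 22698 with low counts. Libraries were scaled by TMM, with factors of 0.917, 1.02, 0.943 and 0.976 for wild type replicates 1 to 4 and 1.04, 1.07 and 1.04 for knockout replicates 3 to 5. A quasi-likelihood model with group as its only term was fitted to all 7 libraries, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Values in CPM are TMM scaled. Errors on CPM are SDs over libraries and errors on log2 fold changes are standard errors from the fit.

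The comparison, the model, the threshold, the rule for named genes, 33 gene lists and most alternatives were chosen before the data were examined. The rule named Pcbp2, Pcbp1, Pcbp3, Pcbp4 and Hnrnpk. It named the 10 called genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 5 CPM whose groups did not overlap, leaving out predicted and clone names. It also named the 5 most abundant called genes in each direction and, for each list, up to 4 members with the smallest p. Of the 10 genes with the largest rise, 1 is not reported here. The lists hold 684 genes, of which 626 were tested. They cover poly(C)-binding and hnRNP proteins, embryonic and adult globins, haem synthesis, erythroid, megakaryocyte, stem, granulocyte, macrophage, mast and lymphoid cells, hepatoblasts, biliary, endothelial, stellate and mesothelial cells, and neighbouring gut, muscle and neural tissue. They also cover DNA replication, mitosis, p53 targets, interferon, hypoxia, iron storage, cholesterol synthesis, the unfolded protein response, heat shock, mitochondrially encoded, ribosomal protein, histone, sex-linked and imprinted genes. Each list with at least 3 tested members was tested with camera of limma 3.58.1, which asks whether its genes rank above or below the other genes, with a preset correlation of 0.01 between genes, adjusted over the 33 lists. An estimated correlation was used as an alternative, as was fry, which asks whether a list's genes move, on balance, in one direction.

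On data simulated from the means, library sizes and dispersions of the real libraries, with 200 changed genes, the edgeR fit recovered 31.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 98.5% of those changed 4-fold. Of its 147 calls, 14 were false, or 9.52%, more than the threshold of 5% in name. Genes were simulated independently of each other, and the changed ones were not taken from the least abundant genes. These shares therefore do not cover correlated genes or changes at the lowest counts.

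Shares of reads per library were compared by two-sided exact permutation tests over the 35 splits of the 7 libraries into 4 and 3, whose smallest p is 0.0286, adjusted over 11 measures. Reads in no annotated gene made up 5.44 ± 0.43% of reads in wild type and 7.29 ± 0.47% in knockout (exact permutation p = 0.0286; adjusted 0.0786). Reads aligned to more than 1 place made up 17.0 ± 1.86% and 13.3 ± 1.81% (exact permutation p = 0.0571; adjusted 0.126). The 50 most abundant genes took 19.1 ± 1.39% and 15.3 ± 0.779% of the reads assigned to genes (exact permutation p = 0.0286, adjusted 0.0786).

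The alternatives were RLE size factors, total-count scaling, globin genes left out, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, sex-linked genes left out, each library left out in turn, limma-voom, DESeq2 1.42.0 and a replicate block. The block uses the number in each title, although only 2 numbers occur in both groups and the labels do not say that equal numbers share a litter or day. Its comparison of knockout with wild type therefore rests on replicates 3 and 4 of each group. Libraries whose number occurs in a single group are fitted by their own term and add nothing to it. A correction of each library for gene length and GC content and a covariate for Y-linked expression were added after the data were seen.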

Results

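The data are messenger RNA sequencing counts per gene from mouse fetal liver at 12.5 days post coitum, when the liver is the main site of blood formation. There were 7 libraries, 4 from wild type and 3 from Pcbp2 knockout, and the labels give no sex, litter or batch. Reads assigned to genes numbered 32240949, 40090040, 38753337 and 44544889 in wild type replicates 1 to 4, and 31898339, 42378821 and 33593856 in knockout replicates 3 to 5. Of 38924 genes in the files, 16226 had enough reads to be tested. At these depths 3 reads, the most that a count of 0 allows, correspond to between 0.0662 and 0.102 CPM (read counts scaled to library size), and such floors cover counting error only. The p-values measure the spread between these libraries, because the labels do not say that each came from a separate animal.

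The only comparison, knockout against wild type, asks what the loss of Pcbp2 does to the fetal liver transcriptome. Pcbp2, a protein that binds C-rich stretches of RNA and acts in splicing, RNA stability and translation, fell from 295 ± 86.9 CPM (SD, n = 4) to 1.95 ± 0.486 CPM (SD, n = 3). The log2 fold change was -7.26 ± 0.34 (SE; edgeR adjusted p = 1.29e-05), a 151-fold difference. Pcbp2 (ENSMUSG00000056851.7) lies on chromosome 15 from 102470539 to 102500061 in build mm10. Its knockout libraries held 74, 63 and 78 reads, and the wild-type libraries 4868, 13479, 12692 and 14682. Wild type replicate 1 stood apart at 165 CPM, against 329, 347 and 338 CPM in the other wild-type libraries. Pcbp1, the intronless relative of Pcbp2, had 299 ± 23.3 CPM in wild type and 277 ± 15.2 CPM in knockout, a log2 difference of -0.11 ± 0.10 (edgeR adjusted p = 0.561). The log2 differences of the other poly(C)-binding genes were 0.18 ± 0.13 for Pcbp3 (edgeR adjusted p = 0.451), 0.46 ± 0.21 for Pcbp4 (edgeR adjusted p = 0.238, but under 0.05 with the replicate block) and 0.05 ± 0.10 for Hnrnpk (edgeR adjusted p = 0.827). In the list of 13 poly(C)-binding and hnRNP genes, Pcbp2 was the 1 member that passed, both over all genes and adjusted over the list alone. The list median was 0.08, its mean -0.46 because of Pcbp2, and its test pointed down without passing (camera adjusted p = 0.248, but 0.000393 without wild type replicate 1 and 0.000211 with the replicate block). The median was 0.03 without wild type replicate 2 and 0.12 without wild type replicate 1.

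**Figure D1:**
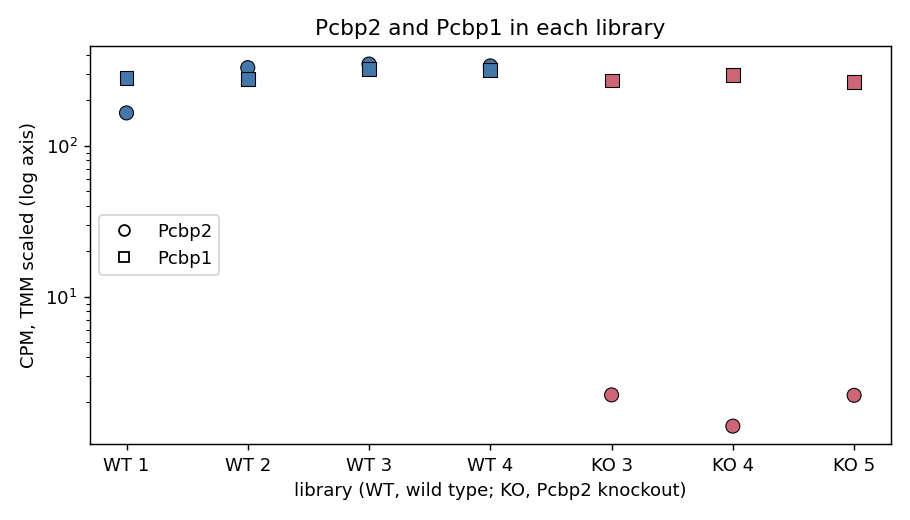
CPM on a log axis for Pcbp2 (circles) and Pcbp1 (squares) in each of the 4 wild-type (blue) and 3 knockout (red) libraries. Pcbp2 lies between 1.39 and 2.24 CPM in the knockout libraries and between 165 and 347 CPM in the wild-type ones, while Pcbp1 stays near 300 CPM in both groups.

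In the knockout livers 258 genes rose and 556 fell (edgeR adjusted p under 0.05), and 87 of the former and 230 of the latter changed at least 2-fold. The knockout libraries lay entirely above the wild-type ones for 255 of the rising genes and entirely below for 553 of the falling genes. Among all tested genes 20.6% separated in this way, against 5.71% by chance, and 3535 genes had an unadjusted p under 0.05. The proportion of falling genes depended on the scaling. Scaling by total counts moved the median log2 fold change of all genes from 0.01 to 0.14 and gave 651 rising and 393 falling genes, so that 37.6% of the called genes fell instead of 68.3%. Changes are therefore relative to the typical gene. The counts also moved with single libraries. Rising genes numbered 148 without wild type replicate 1, 418 without wild type replicate 2, 79 without wild type replicate 3 and 93 without wild type replicate 4. They numbered 107 without knockout replicate 4 and 24 without knockout replicate 5. Falling genes numbered 363 without wild type replicate 1, 286 without wild type replicate 3, 324 without wild type replicate 4, 242 without knockout replicate 4 and 116 without knockout replicate 5.

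Adult globin transcripts fell. Hbb-bs, an adult beta-globin gene, fell from 18286 ± 5500 to 2188 ± 840 CPM, an 8.36-fold difference (log2 -3.06 ± 0.31, edgeR adjusted p = 0.00138). Hbb-bt, the adjacent adult beta-globin gene, fell 8.72-fold, from 8760 ± 4002 to 1004 ± 413 CPM (log2 -3.12 ± 0.40, edgeR adjusted p = 0.00437). Hba-a1, adult alpha-globin, fell from 36614 ± 6980 to 9515 ± 1150 CPM (log2 -1.94 ± 0.18, edgeR adjusted p = 0.00133), although its reads cannot be told with certainty from those of its near copy Hba-a2. All 4 adult globin genes tested fell, also adjusted over the list alone, with a median of -2.58 (camera adjusted p = 1.78e-21). This was the only list still past the threshold with an estimated correlation (adjusted p = 0.0418 with an estimated correlation). Adult globins took 6.09 ± 1.19% of the reads assigned to genes in wild type and 1.33 ± 0.171% in knockout (two-sided exact permutation p = 0.0286, the smallest the design allows, and 0.0786 adjusted over 11 library measures).

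The embryonic globins moved apart from the adult ones. Hbb-y, embryonic epsilon-type globin, had 8176.5 ± 1663 CPM in wild type and 9408 ± 3463 CPM in knockout (log2 0.20 ± 0.24, edgeR adjusted p = 0.677). Its sign was not settled, with -0.08 without knockout replicate 5 and 0.45 without knockout replicate 3. The log2 difference was 1.0 ± 0.30 for Hba-x (edgeR adjusted p = 0.0897) and 0.82 ± 0.23 for Hbb-bh1 (edgeR adjusted p = 0.0751). None of the 3 passed over all genes with edgeR or limma-voom, 1 did with DESeq2, 2 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone; the list ranked higher with a median of 0.82 (camera adjusted p = 0.0402; adjusted p = 0.503 with an estimated correlation). Hba-x passed without knockout replicate 3 (edgeR adjusted p = 0.0258), with no filter on low counts (0.0322) and with the replicate block (0.0105). Hbb-bh1 passed with total-count scaling (0.0360), with no filter on low counts (0.0279), with the length and GC correction (0.0188) and with DESeq2 (0.00694). The list call ended with total-count scaling (0.0579), with limma-voom (0.0629), with at least 5 CPM in 3 libraries (0.0649) and with the Y-linked covariate (0.0631). It also ended without wild type replicate 2 (0.0879), wild type replicate 3 (0.0668), wild type replicate 4 (0.0561) or knockout replicate 5 (0.163). The median was 0.47 without knockout replicate 5 and 0.46 with the replicate block.

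**Figure D2:**
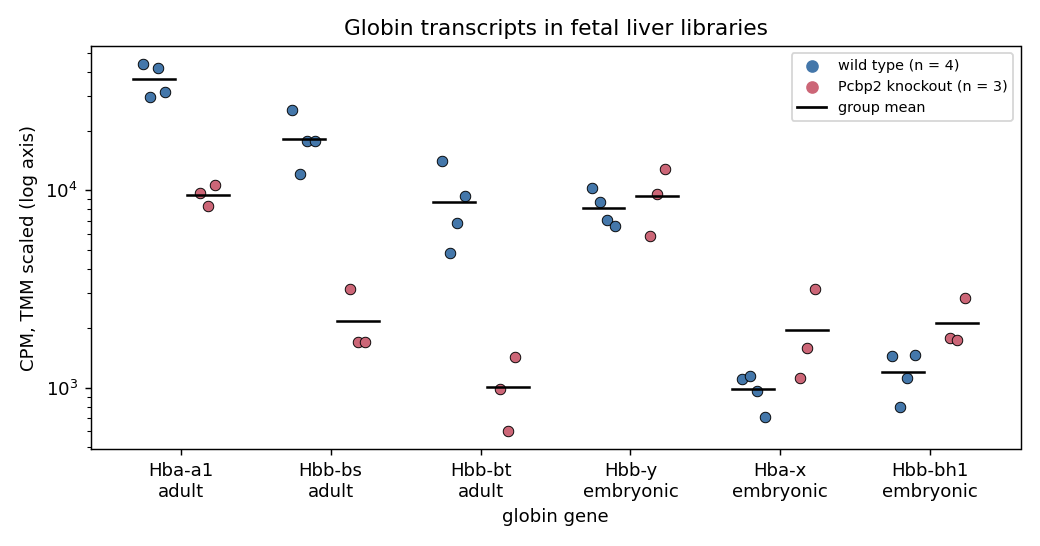
CPM on a log axis for 3 adult and 3 embryonic globin genes, with each of the 4 wild-type (blue) and 3 knockout (red) libraries as a point and group means as lines. All knockout points lie below all wild-type points for Hba-a1, Hbb-bs and Hbb-bt, while Hbb-y averages 8176.5 CPM in wild type and 9408 CPM in knockout.

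Genes of red cell maturation and haem synthesis ranked lower. In the erythroid differentiation list 16 of 28 members fell, 25 adjusted over the list alone, with a median of -0.93 (camera adjusted p = 4.5e-27; adjusted p = 0.295 with an estimated correlation). Trim10, an erythroid ubiquitin ligase, fell from 239 to 75.5 CPM (log2 -1.66 ± 0.20, edgeR adjusted p = 0.00378). Rhd, the Rh blood group antigen of the red cell membrane, fell from 195 to 68.4 CPM (log2 -1.51 ± 0.19, edgeR adjusted p = 0.00434). Fam46c, a poly(A) polymerase, fell from 276 to 90.4 CPM (log2 -1.61 ± 0.21, edgeR adjusted p = 0.00434). In the haem synthesis and iron uptake list 8 of 15 members fell, 12 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 2.64e-14; adjusted p = 0.295 with an estimated correlation). Alas2, the rate-limiting erythroid enzyme of haem synthesis, fell from 639 ± 151 to 186 ± 27.5 CPM (log2 -1.78 ± 0.19, edgeR adjusted p = 0.00227), and Alad, the next enzyme of the pathway, fell by 0.87 on the log2 scale (edgeR adjusted p = 0.00595). Leaving out single libraries changed these counts but not the 2 list calls. The erythroid count was 9 without wild type replicate 3, 9 without knockout replicate 4 and 7 without knockout replicate 5, and the haem count 4, 3 and 2 in the same order. Over all alternatives the erythroid count ran from 7 to 25 and the haem count from 2 to 13, both highest with the replicate block.

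Platelet and macrophage genes also ranked lower. In the megakaryocyte and platelet list 11 of 26 members fell, 16 adjusted over the list alone, with a median of -0.56 (camera adjusted p = 3.49e-14; adjusted p = 0.295 with an estimated correlation). Ppbp, a platelet chemokine, fell from 91.0 ± 14.7 to 31.2 ± 4.08 CPM (log2 -1.55 ± 0.15, edgeR adjusted p = 0.00133), and Pf4, platelet factor 4, fell from 131 to 61.4 CPM (log2 -1.10 ± 0.13, edgeR adjusted p = 0.00363). In the macrophage and monocyte list 11 of 24 members fell, 14 adjusted over the list alone, with a median of -0.62 (camera adjusted p = 2.78e-12; adjusted p = 0.295 with an estimated correlation). Marco, a scavenger receptor, fell from 5.38 ± 1.92 to 0.722 ± 0.255 CPM (log2 -2.88 ± 0.37, edgeR adjusted p = 0.00451), and C1qb, a complement component made by macrophages, fell from 45.5 to 23.6 CPM (log2 -0.95 ± 0.12, edgeR adjusted p = 0.00434). The megakaryocyte count was 6 with total-count scaling, 4 without wild type replicate 3, 5 without wild type replicate 4, 3 without knockout replicate 4 and 2 without knockout replicate 5. Over all alternatives it ran from 2 to 18, highest with the replicate block. The macrophage count was 7 with total-count scaling, 5 without wild type replicate 4, 5 without knockout replicate 4 and 2 without knockout replicate 5.

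Smaller blood lineage lists ranked lower with few members past the threshold. In the granulocyte list 1 of 18 members fell, 3 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 0.000148; adjusted p = 0.567 with an estimated correlation); it was Ctsg, the neutrophil protease cathepsin G (log2 -1.75, edgeR adjusted p = 0.0136, but 0.0745 without knockout replicate 5). The granulocyte count was 3 without wild type replicate 2 and 8 without knockout replicate 3, where the median was -1.17, and it was 0 without knockout replicate 5, where the median was -0.34 (camera adjusted p = 0.0193). In the mast cell, basophil and eosinophil list 1 of 6 fell, 3 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 0.00577, but 0.25 with at least 5 CPM in 3 libraries, where the median was -0.28; adjusted p = 0.392 with an estimated correlation). That member was Gzmb, a granule protease, at 0.577 CPM in wild type and 0.0772 CPM in knockout (edgeR adjusted p = 0.0337). Its call ended without wild type replicate 1, 3 or 4 or knockout replicate 3 or 4, with adjusted p up to 0.0776, and with the Y-linked covariate. In the lymphoid list 1 of 10 fell, 3 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.0255; adjusted p = 0.295 with an estimated correlation). It was Thy1, a T cell surface glycoprotein (log2 -1.69, edgeR adjusted p = 0.0261), lost without wild type replicate 1 or 4 or knockout replicate 3, 4 or 5 (up to 0.0948). The lymphoid list call ended without wild type replicate 1 (0.0889), 2 (0.0514) or 4 (0.0898), without knockout replicate 4 (0.0834), with the replicate block (0.11) and with the length and GC correction (0.0644), and its median was -1.13 with no filter on low counts. The stem and progenitor list ranked neither way (median 0.29, camera adjusted p = 0.304), with 2 of 21 members lower and, adjusted over the list alone, 4 higher and 4 lower. The 2 were Spi1, the myeloid transcription factor PU.1 (log2 -0.86 ± 0.13, edgeR adjusted p = 0.00676, but 0.0518 without knockout replicate 5), and Flt3, a progenitor receptor kinase (log2 -1.78, edgeR adjusted p = 0.0136, lost without knockout replicate 4 or 5, up to 0.065). The list median was 0.17 without knockout replicate 3. Leaving out wild type replicate 1 or 2 or knockout replicate 4 gave 1 member higher, and leaving out knockout replicate 5 gave 0 lower. Over all alternatives from 0 to 5 stem and progenitor genes rose and from 0 to 4 fell.

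Endothelial genes ranked higher. In this list 6 of 24 members rose, 10 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 5.35e-09; adjusted p = 0.383 with an estimated correlation). Emcn, a sialomucin of venous and capillary endothelium, rose from 7.10 ± 1.14 to 14.2 ± 1.23 CPM (log2 1.0 ± 0.15, edgeR adjusted p = 0.00676). Pecam1, an adhesion molecule of endothelial junctions, rose from 24.6 to 42.6 CPM (log2 0.79 ± 0.15, edgeR adjusted p = 0.0162, but 0.0575 without knockout replicate 5). Over all alternatives from 1 to 9 members rose, 9 with total-count scaling, with the length and GC correction and with DESeq2. Their number was 3 without wild type replicate 1, 3 without wild type replicate 4, 2 without knockout replicate 4 and 1 without knockout replicate 5.

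In the muscle and diaphragm list 2 of 19 members rose, while adjusted over the list alone 3 rose and 1 fell, with a median of 0.57 (camera adjusted p = 0.0061; adjusted p = 0.651 with an estimated correlation). Both are genes of heart muscle, and whether their reads came from liver cells or from neighbouring tissue in the samples was not tested. Myh6, the alpha myosin heavy chain of the atria, had 37.9, 2.18 and 11.4 CPM in knockout replicates 3, 4 and 5, against 0.22 to 0.782 CPM in wild type (edgeR adjusted p = 0.00871, limma-voom 0.0868). Nppa, atrial natriuretic peptide, had 10.2, 0.309 and 3.05 CPM in the same knockout libraries and at most 0.0488 CPM in wild type (edgeR adjusted p = 0.0104, limma-voom 0.0809). The number of members that rose was 4 without knockout replicate 4, 0 with limma-voom and at most 5, with the replicate block. The list call ended without wild type replicate 1 (0.0639) or knockout replicate 3 (0.0872), with total-count scaling (0.0598), with limma-voom (0.0629) and with at least 5 CPM in 3 libraries (0.227). The median was 0.33 without wild type replicate 1, 0.27 without wild type replicate 3, 0.26 without knockout replicate 3, 0.29 without knockout replicate 5, 0.25 with the replicate block and 0.30 with at least 5 CPM in 3 libraries.

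Hypoxia and glycolysis genes ranked higher, with 2 of 31 members past the threshold and, adjusted over the list alone, 14 higher and 1 lower. The list median was 0.50 (camera adjusted p = 1.74e-06; adjusted p = 0.567 with an estimated correlation). Kdm3a, a hypoxia-induced histone demethylase, rose from 78.4 to 124 CPM (log2 0.66 ± 0.13, edgeR adjusted p = 0.0226), but its call ended without wild type replicate 3 or 4 or knockout replicate 4 or 5 (up to 0.0929). Ero1l, an oxidase of the endoplasmic reticulum, rose by 0.54 on the log2 scale (edgeR adjusted p = 0.0476), a call that ended whichever of the 7 libraries was left out (up to 0.132). Without knockout replicate 4 the median was 0.26 (camera adjusted p = 0.0231) and 1 member fell. Over all alternatives from 0 to 12 members rose: 12 with the replicate block, 7 with no filter on low counts, 5 with total-count scaling, and 1 with limma-voom, with the length and GC correction and with the Y-linked covariate. The Ero1l call ended under these last 3. DESeq2 called 11 members, counting both directions. Leaving out knockout replicate 3 gave 11 rising members, leaving out wild type replicate 1 or 2 gave 1, and leaving out wild type replicate 3 or 4 or knockout replicate 4 or 5 gave 0.

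Interferon response genes ranked lower in knockout, with all 27 log2 differences below 0 and a median of -1.08 (camera adjusted p = 4.33e-10; adjusted p = 0.503 with an estimated correlation). Of these, 3 fell over all genes and 18 adjusted over the list alone. Gbp2, an interferon-induced GTPase, fell from 16.9 ± 2.56 to 7.96 ± 0.338 CPM (log2 -1.09 ± 0.14, edgeR adjusted p = 0.00489). Oasl2, an interferon-induced oligoadenylate synthetase-like gene, and Cxcl10, an interferon-induced chemokine, also fell (log2 -1.03 and -1.34, edgeR adjusted p = 0.0401 and 0.0362). The Oasl2 call ended without wild type replicate 1 or knockout replicate 3, 4 or 5 (up to 0.13), and that of Cxcl10 without wild type replicate 1 or 3 or knockout replicate 3, 4 or 5 (up to 0.112). The wild-type libraries were uneven: Isg15, a ubiquitin-like interferon-induced protein, had 11.8, 12.4, 1.86 and 1.89 CPM in wild type replicates 1 to 4 and 0.635, 0.861 and 1.37 CPM in knockout (edgeR adjusted p = 0.0548, but 0.0414 without wild type replicate 3 and 0.0368 without wild type replicate 4). With the replicate block the median was -0.34 (camera adjusted p = 0.00383) and 6 members fell. DESeq2 called 14 members, no filter on low counts gave 11, total-count scaling 2, and limma-voom and the Y-linked covariate 1 each. Oasl2 lost its call under these last 3 and Cxcl10 with limma-voom and the Y-linked covariate. The number of members that fell was 8 without wild type replicate 4 and 1 without wild type replicate 1 or any of the 3 knockout libraries.

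The lists of DNA replication, mitosis, ribosomal protein and histone genes ranked lower. In the DNA replication list 0 of 28 members passed, also adjusted over the list alone, while the list as a whole ranked lower (median -0.17, or -0.05 with total-count scaling, camera adjusted p = 0.00202; adjusted p = 0.62 with an estimated correlation). At an unadjusted edgeR p under 0.05 there were 8 DNA replication genes, DESeq2 called 3 and limma-voom 0. The number that fell was 6 with the replicate block, 3 without wild type replicate 2 and 1 without knockout replicate 3. In the mitosis list 2 of 27 fell, the same number adjusted over the list alone (median -0.15, camera adjusted p = 0.00654; adjusted p = 0.667 with an estimated correlation), and the list call ended without wild type replicate 1 (0.0717) or knockout replicate 4 (0.134). The mitosis median was -0.10 and -0.09 without these, -0.25 without wild type replicate 2, -0.26 without knockout replicate 3 and -0.02 with total-count scaling. The members that fell were Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (log2 -0.67, edgeR adjusted p = 0.0153, lost without knockout replicate 4 or 5, up to 0.0971), and Birc5, survivin (log2 -0.40, edgeR adjusted p = 0.0475). The Birc5 call was lost without any library other than wild type replicate 2 (up to 0.179), and with total-count scaling, limma-voom, the Y-linked covariate and sex-linked genes left out. From 0 to 4 mitosis genes fell over all alternatives. Among cytosolic ribosomal protein genes 2 of 42 fell, 3 adjusted over the list alone (median -0.23, camera adjusted p = 1.89e-05; adjusted p = 0.622 with an estimated correlation). The median was -0.11 without knockout replicate 3 (camera adjusted p = 0.0356), -0.10 with total-count scaling and -0.13 with the length and GC correction. The members that fell were Rpl22 and Rpl34 (log2 -0.50 and -0.55, edgeR adjusted p = 0.0325 and 0.0433), lost with total-count scaling and without any library other than wild type replicate 2 (up to 0.1 and 0.14); 4 members fell without wild type replicate 2 and 6 with the replicate block. Of the replication-dependent histone genes 3 of 18 fell, 4 adjusted over the list alone (median -0.39, camera adjusted p = 0.00156; adjusted p = 0.295 with an estimated correlation). The histone median was -0.23 without knockout replicate 3, -0.64 without knockout replicate 5, -0.26 with the length and GC correction and -1.24 with at least 5 CPM in 3 libraries. How fully the mRNA libraries captured histone transcripts was not tested, so these values cover only the captured part. Hist1h1c, a linker histone, fell from 46.8 to 15.5 CPM (log2 -1.60 ± 0.19, edgeR adjusted p = 0.00315), Hist1h4i fell by 1.24 on the log2 scale (edgeR adjusted p = 0.00784), and Hist1h1d, another linker histone, by 1.78 (edgeR adjusted p = 0.0144, but 0.0796 without knockout replicate 5).

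**Figure D3:**
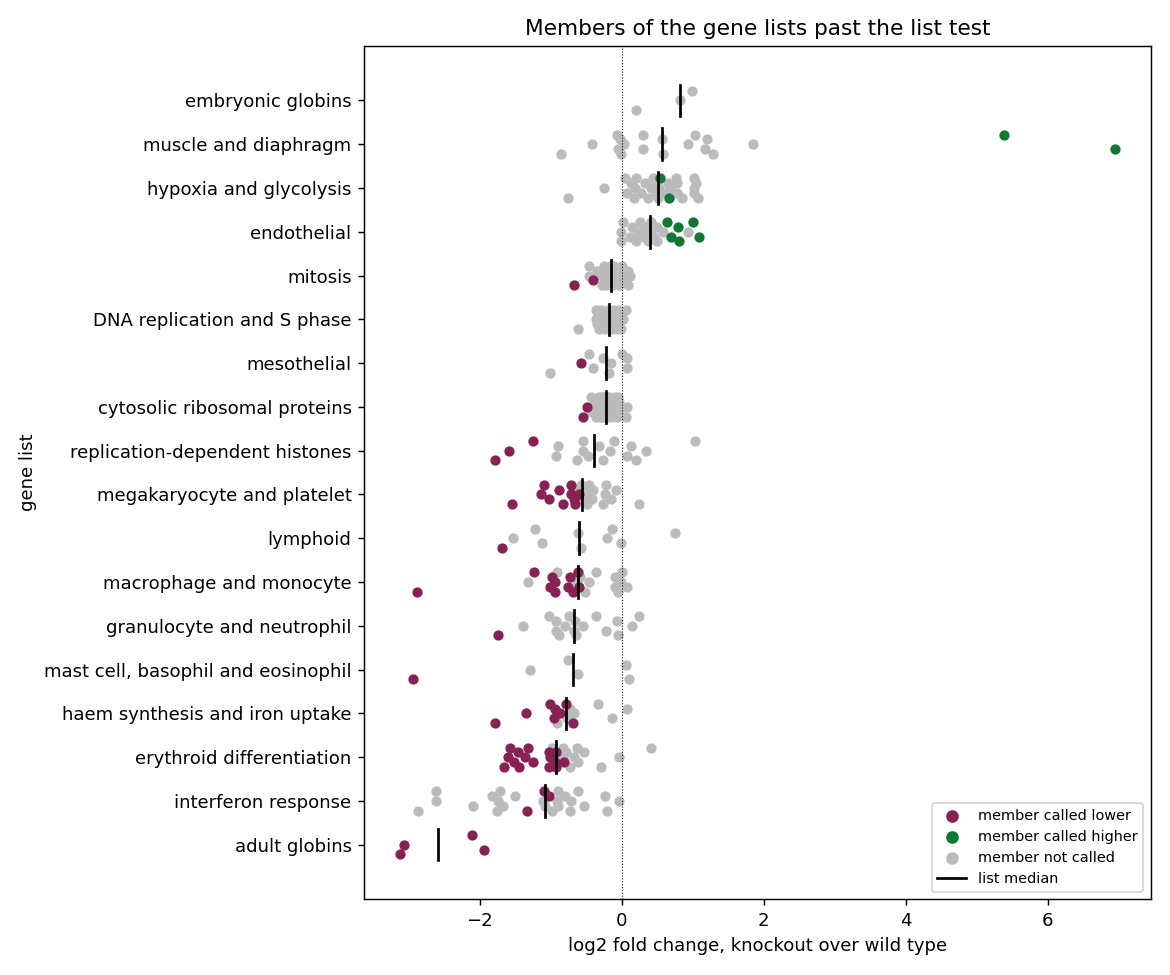
The log2 fold change, knockout over wild type, of every member of the 18 gene lists past the list test, with members that rose in green, members that fell in purple, the rest in grey and list medians as black bars. The medians run from -2.58 for adult globins to 0.82 for embryonic globins, and the point farthest to the right is Nppa, whose fitted value rests on wild-type levels at or under 0.0488 CPM.

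In the hepatoblast and hepatocyte list 1 of 34 members fell, the same number adjusted over the list alone (median -0.18, camera adjusted p = 0.248). It was Ahsg, the plasma protein fetuin-A, which went from 104 to 45.6 CPM (log2 -1.18, edgeR adjusted p = 0.0213, lost without knockout replicate 4 or 5, up to 0.0998). Without wild type replicate 2 the hepatoblast list ranked lower (median -0.31, 0.000449) with 4 members that fell, and the biliary list ranked higher (0.0404) with 2 that rose. Without wild type replicate 3 the hepatoblast test pointed up instead, with a median of 0.00 (0.982), and the median was -0.09 without wild type replicate 4 and -0.06 without knockout replicate 5. With the replicate block the hepatoblast list also ranked lower (5.59e-05), with 11 members that fell and 1 that rose, and the biliary list higher (0.0455), with 3 that rose. In the biliary list 0 of 10 passed with edgeR or limma-voom and 2 with DESeq2, 2 had an unadjusted p under 0.05, and 2 were higher adjusted over the list alone (median 0.26, camera adjusted p = 0.294). The biliary median was 0.13 without knockout replicate 3 and 0.06 without knockout replicate 4, where 1 member rose. In the stellate and mesenchymal list 1 of 26 rose and 3 fell, against 2 and 3 adjusted over the list alone (median -0.13, camera adjusted p = 0.491). The stellate median was -0.23 without wild type replicate 1 and -0.03 without wild type replicate 2, where the test pointed up. The 3 that fell were Lum, a matrix proteoglycan, Lrat, the vitamin A storing enzyme of stellate cells, and Mgp, matrix Gla protein (log2 -0.64, -2.23 and -1.51, edgeR adjusted p = 0.0135, 0.0161 and 0.0259). Acta2, smooth muscle actin, rose (log2 0.59, edgeR adjusted p = 0.0483). Without knockout replicate 5 the calls of Lum (0.0897), Lrat (0.079) and Mgp ended. That of Mgp also ended without wild type replicate 1 or 3 or knockout replicate 3 (up to 0.125) and with the Y-linked covariate, and that of Acta2 without any library other than wild type replicate 2 (up to 0.155), with at least 5 CPM in 3 libraries and with the Y-linked covariate. Over all alternatives from 0 to 5 stellate and mesenchymal genes rose and from 0 to 3 fell. In the mesothelial list 1 of 10 fell, 4 adjusted over the list alone (median -0.22, camera adjusted p = 0.0142; adjusted p = 0.567 with an estimated correlation), and the list call ended without wild type replicate 2 (0.088) or knockout replicate 3 (0.116), with at least 5 CPM in 3 libraries (0.0649) and with the replicate block (0.138). The mesothelial median was -0.10 with total-count scaling and -0.15 with the replicate block. The member that fell was Gpm6a, a membrane glycoprotein (log2 -0.58, edgeR adjusted p = 0.0258, lost with total-count scaling and without wild type replicate 1 or 4 or knockout replicate 4 or 5, up to 0.139).

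The remaining lists did not pass the list test. Of imprinted genes 2 of 17 rose, the same number adjusted over the list alone, with a median of -0.03 but a mean of 0.09 and a test that pointed up (camera adjusted p = 0.248); the median was 0.10 with total-count scaling, 0.12 without knockout replicate 3 and -0.13 without knockout replicate 4. Peg10, a retrotransposon-derived gene, rose from 535 ± 92.2 to 1140 ± 139 CPM (log2 1.09 ± 0.15, edgeR adjusted p = 0.00552), and Meg3, a long noncoding RNA, from 290 to 491 CPM (log2 0.76, edgeR adjusted p = 0.0145, but 0.0632 without knockout replicate 5). Of iron storage and export genes 1 of 16 fell, the same number adjusted over the list alone (median -0.16, camera adjusted p = 0.248; median -0.08 without knockout replicate 4 and -0.09 without knockout replicate 5). It was Ftl1, ferritin light chain, which went from 2045 ± 55.8 to 1269 ± 197 CPM (log2 -0.69 ± 0.13, edgeR adjusted p = 0.0153, but 0.0903 without knockout replicate 5). Among p53 targets 1 of 24 rose and 1 fell, against 2 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.491), with a median of 0.08 without knockout replicate 4 or 5. Btg2, an antiproliferative gene, fell (log2 -1.21, edgeR adjusted p = 0.00896, but 0.06 without knockout replicate 5), and Plk2, a polo-like kinase, rose (log2 0.70, edgeR adjusted p = 0.0348, lost without wild type replicate 1, 3 or 4 or knockout replicate 4 or 5, up to 0.146, and with the Y-linked covariate). In the unfolded protein and amino acid list 1 of 26 rose, while adjusted over the list alone 2 rose and 1 fell (median 0.06, camera adjusted p = 0.486). The median was 0.11 without wild type replicate 4 and -0.01 without wild type replicate 2, where the test pointed down. The member was Stc2, stanniocalcin (log2 1.67, edgeR adjusted p = 0.0468, lost without any library other than knockout replicate 3, up to 0.139, and with limma-voom and the Y-linked covariate); 3 members rose without knockout replicate 3 and 2 fell without wild type replicate 2. Over all alternatives at most 3 iron storage genes fell and 1 rose, and at most 2 p53 targets rose and 2 fell.

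No member passed, over all genes or adjusted over the list alone, among 12 genes of neighbouring gut, pancreas and stomach (median -0.26, camera adjusted p = 0.48), 22 of cholesterol synthesis (median 0.06, camera adjusted p = 0.248), 19 of heat shock and immediate early response (median 0.12, camera adjusted p = 0.54) and 11 mitochondrially encoded genes (median 0.14, camera adjusted p = 0.491, but 0.00687 without knockout replicate 4). These medians hung on single libraries. The gut median was 0.01 without wild type replicate 2, where the test pointed up, and -0.66 without knockout replicate 5. The cholesterol median was 0.15 without wild type replicate 3 (camera adjusted p = 0.0726) and 0.13 without knockout replicate 3 (0.0551). The heat shock median was 0.06 without wild type replicate 2, 0.21 without knockout replicate 3 and 0.08 without knockout replicate 4, where the test pointed down. The mitochondrial median was 0.32 without knockout replicate 4, 0.06 without wild type replicate 2 and -0.06 without knockout replicate 3, where the test pointed down. At an unadjusted edgeR p under 0.05 there were 2, 2, 3 and 0 members in this order, limma-voom called 0 in each, and DESeq2 called 1 gut, pancreas and stomach gene and 0 in the others. Alternatives gave some calls: 2 cholesterol genes rose with total-count scaling, where the median was 0.18, and with the replicate block 3 gut, pancreas and stomach genes fell and 1 rose, 2 heat shock genes fell and 1 rose, and 1 mitochondrial gene fell. Without wild type replicate 2, 1 heat shock gene fell. With edgeR, limma-voom and DESeq2, and at an unadjusted edgeR p, 0 members were past 0.05 among 13 neural and neural crest genes, whose median of -0.10 and mean of -0.25 lay below 0 while the test pointed up (camera adjusted p = 0.815); the median was 0.34 without wild type replicate 2 and -0.48 without wild type replicate 3. With the replicate block the median was 0.57, 1 member rose and the list ranked higher (0.00309). Sex-linked genes gave 0 of 6 by edgeR, limma-voom and DESeq2 and 0 at an unadjusted p (median 0.58, camera adjusted p = 0.491, but 0.0455 with the replicate block), with a median of 0.10 without knockout replicate 5 and 1.38 without wild type replicate 1. Xist, the RNA of the inactive X chromosome, had 31, 46595, 48104 and 42 reads in wild type replicates 1 to 4 and 73130, 37 and 34 reads in knockout replicates 3 to 5, so that libraries with high Xist occurred in both groups.

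Among genes with a mean of at least 5 CPM and groups that did not overlap, Pcbp2 aside and predicted or clone names left out, Hbb-bt, Hbb-bs and Snx22, a sorting nexin, fell most. Snx22 went from 28.9 to 4.16 CPM (log2 -2.80 ± 0.28, edgeR adjusted p = 0.00138). Next came Mir451, the precursor locus of an erythroid microRNA, from 12.3 to 1.93 CPM (log2 -2.67 ± 0.38, edgeR adjusted p = 0.00595), and Depdc1b, a regulator of the cell cycle, from 29.3 to 4.66 CPM (log2 -2.66 ± 0.15, edgeR adjusted p = 3.02e-05). Tmcc2 fell from 414 to 70.9 CPM, Col6a6, a collagen chain, from 18.9 to 3.25 CPM, and Sowaha by 2.50 on the log2 scale. Irgm2 and Igtp, immunity-related GTPases, fell by 2.55 and 2.49 on the log2 scale, but their annotated spans overlap on the same strand, so their reads cannot be assigned with certainty.

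Of the genes that rose most by the same rule, Myh6 led and Ankrd1, a stress-responsive gene of heart and skeletal muscle, went from 1.06 to 10.4 CPM (log2 3.27 ± 0.50, edgeR adjusted p = 0.00782). Its rise was uneven, with 18.3, 3.91 and 8.93 CPM in knockout replicates 3, 4 and 5 and at most 1.59 CPM in wild type. The neurotrophin receptor Ntrk3 (log2 1.28 ± 0.23), the noncoding RNA Dnm3os (1.20 ± 0.17) and the nuclear receptor Nr2f1 (1.18 ± 0.18) rose with edgeR adjusted p of 0.0147, 0.00595 and 0.00717. Bcat1, a branched-chain amino acid transaminase, rose by 1.22 on the log2 scale (edgeR adjusted p = 0.0136, but 0.0789 without knockout replicate 5). Ndnf, a secreted neurotrophic factor, rose by 2.08 (0.015, lost without knockout replicate 4 or 5, up to 0.0608), and Alx4 by 1.47 (0.023, lost without wild type replicate 3 or 4 or knockout replicate 4 or 5, up to 0.104, and with the Y-linked covariate). Hmga2, a chromatin protein of fetal tissues, was among the most abundant genes that rose, from 503 to 759 CPM (log2 0.59, edgeR adjusted p = 0.0105, but 0.079 without knockout replicate 5). Rpl41, a ribosomal protein gene outside the fixed list, was among the most abundant that fell, from 2821 to 1723 CPM (log2 -0.71, edgeR adjusted p = 0.0188, lost without wild type replicate 4 or knockout replicate 5, up to 0.0748).

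The authors' deposited table, from the same libraries, lists 15548 genes with 632 higher and 1067 lower at an adjusted p of 0.05. The authors' deposited table gives Pcbp2 a log2 fold change of -6.93 (adjusted p = 1.97e-173, DESeq2). Of the genes called with edgeR here, 249 rising and 549 falling genes were also called in the authors' deposited table in the same direction, 798 of 814 or 98.0%, and 0 were called in the opposite direction. At an adjusted p of 0.01 both here and in the authors' deposited table, 166 genes were shared.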

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

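In this part the tests of abundant genes, of a single lower share of red cells, of a younger stage, of knockout RNA in wild type replicate 1 and of a disrupted allele there were chosen only after the results were seen, as was the correction for gene length and GC content. A wild-type library was singled out where its gap to the nearest other one, divided by the range of the group, was above the critical value of the Dixon test, which chance does in about 1 of 20 groups of 4. That happened for 17 of 160 values.

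Adult globin and erythroid genes fell in the knockout, and reads in no annotated gene made up 7.29% of its reads on average, outside the wild-type range of 4.89 to 5.94%. Taking out the globin genes, as planned, left other genes where they were and so tests nothing. With total counts, which keep the pull of abundant genes, 15 of 28 erythroid genes fell, and 16 with TMM, which removes it. The list median moved by -0.13, from -0.80. Total counts moved the median of all genes upward by 0.12, a shift that could not lower erythroid genes whatever this comparison gave. After a correction for gene length and GC content 15 fell, so that trend does not account for the whole pattern. A single lower share of all red cells would lower embryonic globins too, but the log2 fold change of Hbb-y lay 1.73 ± 0.29 above the value that 0.5 of the Hbb-bs change would give (its own change was -0.08 to 0.45 when single libraries were left out, lowest without knockout replicate 5). A younger stage of the knockout livers remains a candidate explanation: the log2 ratio of Alb to Afp, which rises as liver cells mature, differed by -0.45 (wild-type SD 0.16) with overlapping groups, and stage and genotype cannot be told apart here. An effect of the genotype on red cell maturation, or on the replacement of embryonic by fetal liver red cells, stays open as an untested hypothesis.

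Pcbp2 in wild type replicate 1 stood at 165 CPM, against 329 to 347 CPM in the other 3 wild-type libraries. Knockout RNA mixed into this library would place it between the groups at other called genes, but its median position over 510 such genes was -0.14 (quartiles -0.49 and 0.17), on the far side of wild type. Poor quality of the whole library could lower many genes, but 4 of 4329 genes (0.0924%), Pcbp2 included, fell to the Pcbp2 ratio or below. The scaling removes a loss shared evenly by all genes, so this count speaks only to uneven losses. One disrupted allele may account for the ratio of 0.488 to the other wild-type mean (relative SD of the others 0.0272), but Map3k12, which overlaps the end of Pcbp2 and rose in the knockout, was not raised there (21.9 CPM, against 21.4, 16.0 and 19.9). Whether this sample carried such an allele cannot be told from these counts.

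The number of called genes, 814, was reached by 1 of the 35 splits of the 7 libraries into 4 and 3, the real one. The highest other split, wild type replicates 1, 3 and 4 against the rest, called 202 genes. Ranking first of 35 splits corresponds to an exact permutation p of 0.0286, the smallest the design allows. Chance is thus unlikely for the count as a whole but is not excluded. Genes near Pcbp2 were weighed as a sign of flanking DNA or of a local effect of the allele. Of 124 tested genes within 5 Mb, 8 were called (6.45%), against 799 of 15950 elsewhere (5.01%). The odds ratio of 1.31 (interval 0.55 to 2.68; Fisher exact p = 0.409) leaves a local effect open, since an excess up to the upper bound could not be excluded.

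Other wild-type libraries stood apart at single genes, given as values only. Wild type replicate 2 was above the others for Acta2 at 119 CPM (others 75.3 to 82.8), Atf3 at 3.47 (2.35 to 2.53), Cdh6 at 5.83 (1.89 to 2.44), Chga at 6.57 (0.474 to 0.766) and Ednrb at 56.0 (42.2 to 44.4). It was also above them for Mylpf at 26.3 (13.7 to 15.3), Ntrk3 at 6.49 (3.97 to 4.21) and Plk2 at 50.7 (33.0 to 33.5). The same library was below the others for Rps27a at 1900.5 CPM (2159 to 2189), S100a9 at 76.8 (117 to 124) and Urod at 221 (317 to 328). Its ratio of Hbb-y to Hbb-bs was 0.724 (others 0.37 to 0.402). Wild type replicate 1 was below the others for Dlk1 at 699.9 CPM (871 to 906), Ftl1 at 1962 CPM (2070.5 to 2078) and the share of ambiguous reads at 0.447% (0.501 to 0.504%). Wild type replicate 4 was above the others for Myh6 at 0.782 CPM (0.22 to 0.305).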

How the results depend on the processing

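The gene length and GC correction and the Y-linked covariate were chosen only after the data were seen; the other alternatives were planned. The fall of Pcbp2 passed under every alternative run, with log2 fold changes from -7.45 to -7.04 when single libraries were left out. None of the 814 called genes changed sign under any alternative that tested it, and no called list changed direction. Over the alternatives, 2405 values of the 153 named genes other than Pcbp2 kept their side of the threshold. Another 156 in 43 genes no longer passed, and 145 in 48 genes newly passed. Values that passed in neither fit could change sign, as those of Hbb-y did (-0.08 to 0.45 when single libraries were left out). Of 76 called named genes, 76 were still called with DESeq2, 71 with total counts, 69 with limma-voom and 36 without knockout replicate 5. The number of rising genes, 258, became 651 with total counts, 617 with DESeq2 and 428 with the length and GC correction. The number of falling genes, 556, became 1057 with DESeq2. The replicate block gave 852 rising and 1204 falling genes and 7 lists higher, including 234 and 514 of the genes called without it. That comparison rests on replicates 3 and 4 of each group, which leaves very little to estimate the spread from. Its higher counts therefore cannot be read as a gain in power. The deviations of equally numbered libraries correlated across genes at 0.319 and 0.258. Unequally numbered libraries were not set beside them, so these values cannot speak for or against pairing. Only 2 numbers are shared, and pairing is not established. Leaving out 1 library gave from 24 to 418 rising and from 116 to 753 falling genes; fewer libraries lower the power, but why the counts rose without wild type replicate 2 was not tested. Of 4 lists higher, 2 passed with total counts, 2 with limma-voom and 2 with at least 5 CPM in 3 libraries. With an estimated correlation 0 lists were higher and 1 lower. The estimated correlation was 0.736 in the erythroid, 0.826 in the haem and 0.757 in the interferon list, against the preset 0.01. It was 0.000558 in the lymphoid list, which also lost its call. With fry, which compares no list with other genes, 0 lists were higher and 6 lower. Those 6 were the adult globin, megakaryocyte, macrophage, lymphoid, histone and poly(C)-binding lists, the last holding Pcbp2. The erythroid (fry adjusted p = 0.0609) and haem (0.0698) lists did not pass. Otherwise the cause was not tested. The overlap with the authors' deposited table, 798 genes, was 166 at an adjusted p of 0.01 in both, a stricter threshold, and 1631 with DESeq2. For the total counts, block, DESeq2, limma-voom, filter and correction settings the cause was not tested beyond the shift of the median of all genes from 0.01 to 0.14 with total counts. The depth limits genes under about 0.1 CPM, where 3 reads are the floor.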

Other observations

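The genes in this part were chosen after their values were seen, so their tests are descriptive. Mybpc3, cardiac myosin-binding protein C, had 12.3, 1.04 and 3.51 CPM in knockout replicates 3, 4 and 5 and at most 0.322 CPM in wild type (edgeR adjusted p = 0.0126). Tnni3, cardiac troponin I, had 11.7, 1.99 and 4.19 CPM in the same libraries and at most 1.52 CPM in wild type (edgeR adjusted p = 0.0315, lost without wild type replicate 1, 3 or 4 or knockout replicate 3 or 5, up to 0.0839). In these genes, as in Myh6, Nppa and Ankrd1, knockout replicate 3 was the highest and knockout replicate 4 the lowest of the knockout libraries. Whether heart tissue in the samples contributed to these values was not tested. Gabrp, a GABA receptor subunit, rose and had 2.69, 5.91 and 15.6 CPM in knockout replicates 3, 4 and 5 and at most 0.483 CPM in wild type (edgeR adjusted p = 0.00434).

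Igf2bp1, an RNA-binding protein of fetal tissues, rose from 118 ± 4.5 to 168 ± 3.87 CPM (log2 0.51, edgeR adjusted p = 0.008, but 0.0629 without knockout replicate 5). Its relative Igf2bp2 rose by 0.38 on the log2 scale (edgeR adjusted p = 0.0383, lost without wild type replicate 1, 3 or 4 or knockout replicate 4 or 5, up to 0.187), and Lin28a, a repressor of let-7 processing, by 0.60 (edgeR adjusted p = 0.0244, lost without wild type replicate 4 or knockout replicate 3, 4 or 5, up to 0.104). Igf2bp3 gave a log2 difference of 0.29 (edgeR adjusted p = 0.0732) and Lin28b one of -0.03 (edgeR adjusted p = 0.959). Ube2l6, a ubiquitin-conjugating enzyme, fell from 231 to 55.9 CPM (edgeR adjusted p = 0.000491), and E2f2, a transcription factor of the cell cycle, by 1.66 on the log2 scale (edgeR adjusted p = 0.00595). Map3k12, a kinase gene on the opposite strand whose end overlaps that of Pcbp2, rose from 19.8 ± 2.67 to 44.0 ± 4.37 CPM (edgeR adjusted p = 0.00257).

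Wild type replicate 2 was above every other library for Chgb, a granin of secretory granules, at 16.5 CPM (others 0.151 to 0.529), Dbh and Th, enzymes of catecholamine synthesis, at 7.10 and 3.66 CPM, and Agtr2, an angiotensin receptor, at 18.7 CPM. Processed pseudogenes were present in some libraries and near 0 in others. Rps3a3 had 47.0, 49.2, 50.8 and 0 CPM in wild type replicates 1 to 4 and at most 0.0302 CPM in knockout. Rps13-ps1 had 0, 57.2, 50.7 and 0.069 CPM in wild type and 42.4, 53.9 and 0.143 CPM in knockout. Median log2 fold changes ran from -0.16 in the 10% of genes with the shortest spliced length to 0.09 in the 10% with the longest. The calls followed length too. Of the shortest 10% of genes 6.90% fell and 0.808% rose, while of the longest 10% 1.37% fell and 2.80% rose.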
